A study of Gallus gallus with 4 samples.

How the data were processed

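Total RNA from tibial cartilage of white leghorn chicken embryos was hybridized to 4 Affymetrix chicken arrays after biotin labelling, starting from 5 µg of RNA per sample per the labels. Purely transient cartilage (TC), the cartilage that is later replaced by bone, and a dissection of articular cartilage with some adjoining transient cartilage (TC+AC) were each taken at embryonic day 12 (E12, Hamburger-Hamilton stage 38) and day 14 (E14, stage 40). Each of the 4 combinations of tissue and stage was 1 array, so no group had a replicate. How many embryos went into a sample is not given in the sources used here.

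The deposited table held linear intensities, 1 value per probe set and array, for 38535 probe sets. The summary method, the background correction and any scaling of these deposited intensities are not given in the sources used here. The median deposited intensity was 20.6 in TC at E12, 22.7 in TC+AC at E12, 23.1 in TC at E14 and 13.1 in TC+AC at E14. For arrays, their number limits the precision.

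Analyses used R 4.3.3 with limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9. The 96 Affymetrix control probe sets were left out, and the remaining 38439 were quantile normalized, because the floored log2 medians differed by more than 0.1 between arrays (4.36, 4.50, 4.53 and 3.71, in the order above). Values were then floored at the 20th percentile of all normalized values (4.275) and taken to log2. In the platform annotation, 27178 probe sets carried 1 gene symbol, 177 carried several and 11180 carried none; no gene was named from a probe set with several. The probe set with the highest mean log2 value over the 4 arrays stood for each of the 13009 genes, and 7334 genes had more than 1. The 40% of genes with the lowest mean were left out, which left 7805 genes. A RefSeq gene table of the GRCg7b assembly served for names and synonyms and, in 1 check, for the genomic span of genes; no coordinates are printed, since the build behind the array is not given in the sources used here.

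The main test was limma's moderated linear model (lmFit and eBayes) with tissue and stage as additive terms, and Benjamini-Hochberg adjustment over the 7805 genes at 0.05. With 4 arrays and 3 coefficients this leaves 1 residual degree of freedom per gene, to which the fitted prior added 27.0 (prior variance 0.254). The residual is the disagreement between the 2 stages' tissue differences, and the fitted difference is their mean. With most of the variance taken from the prior, a gene's own disagreement carries little weight. A gene can thus pass on a large difference at 1 stage. The test holds no information on the spread between embryos or repeat dissections, and p-values rest largely on the prior shared across genes. Within a stage, within a tissue and for the change of the tissue difference between stages there is no test, and values are given alone. Counts of genes at least 2-fold in the same direction at both stages, or in both tissues, accompany the calls, with the count that independence of the pairs would give.

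Background on each array was the 95th percentile of 541 probe sets for virus genomes (18.9, 19.1, 15.6 and 24.6 on the normalized linear scale, in the order above). Where 1 side of a comparison lay at or below it, the fold is given as a lower bound, with the background in place of the dim value; adjusted p-values come from the fit on measured values. Statements on background refer to the probe set that stands for the gene unless another is named. The model was tested on simulated data for the tissue comparison, with 200 of 7805 genes changed. It recovered 0% of 2-fold, 78% of 4-fold and 99% of 8-fold changes, with 0, 22 and 16 false calls. The simulated noise came from the fitted prior and was equally wide on all 4 arrays. It held no stage effect and no array of differing RNA quality, so these rates need not hold for the real arrays.

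A total of 18 gene lists were fixed before the data were examined: joint and articular cartilage, hypertrophic cartilage, cartilage matrix, BMP, WNT, hedgehog and PTHrP, TGF-beta and FGF, fibrous tissue and tendon, matrix turnover, proliferation, osteoblast, skeletal muscle, endothelium, erythroid cells, leukocytes, nerve, immediate early and heat shock genes, and hypoxia with glycolysis. Of the list entries, 365 were found by symbol, 11 through a synonym and 56 were not found under their names. Some synonyms led to a symbol that elsewhere names a related gene; the parathyroid hormone receptor of the lists is called PTH2R in the annotation, with PTH1R as synonym. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 18 lists. The estimated version rests on the 1 residual degree of freedom and could hardly call any list. Its p-values therefore decide nothing about a list. Within a stage or tissue, a list's median was placed among 10000 random lists of the same size matched on mean expression, as a description of these arrays. In addition, 7 gene families were defined after the values had been seen.

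Named genes followed a rule fixed before the data were examined: the 10 highest and 10 lowest called genes per comparison that were also at least 2-fold at both stages or in both tissues, with genes that did not pass filling up where fewer than 10 did, the 5 highest and 5 lowest by change of the tissue difference between stages, 18 genes of joint and cartilage biology, and up to 4 members of each list with the largest fitted tissue difference. Alternatives were the normalization, the floor, the filter on dim genes, the treatment of several probe sets, the stage term, the prior, the fold threshold and leaving out each array; 3 more were chosen after seeing the data (scaling on the bacterial hybridization controls, genes above background on all 4 arrays, and the E12 pair alone).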

Results

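The data were 4 expression arrays of embryonic chicken tibia, with 1 array for each of TC and TC+AC at E12 and at E14. The comparison of TC+AC with TC addresses which genes mark the cartilage that will persist at the joint surface as opposed to the cartilage that will be replaced by bone. The stages add the change from E12 to E14. The pair of E12 arrays correlated at r = 0.93 across genes and the pair of E14 arrays at r = 0.77. The TC+AC E14 array was the dimmest as deposited and had a 3' over 5' intensity ratio of 7.48 for beta-actin and 3.97 for EF1-alpha. These ratios were 1.99 and 1.45 on the TC E14 array, 3.26 and 1.64 on TC E12 and 4.01 and 1.54 on TC+AC E12.

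**Figure D1:**
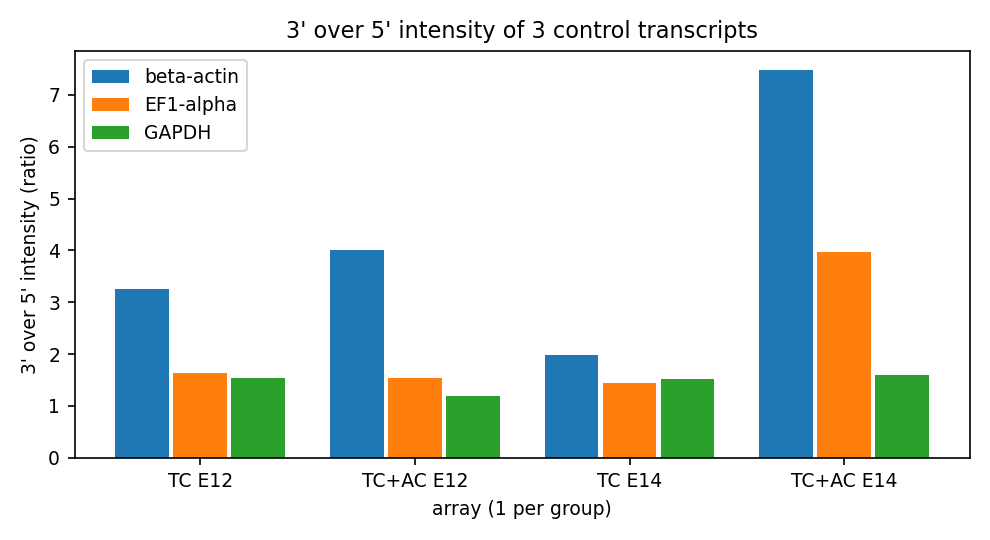
Ratio of 3' to 5' probe set intensity (no unit) for 3 control transcripts on each of the 4 arrays, 1 bar per transcript and array. The beta-actin ratio runs from 1.99 in TC at E14 to 7.48 in TC+AC at E14, while the GAPDH ratio lies between 1.18 and 1.59 on all 4.

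Several genes of hypertrophic and mineralizing cartilage were lower in TC+AC than in TC at both stages. COL10A1, which encodes the collagen X of hypertrophic chondrocytes, was 12.6-fold lower at E12 and 12.2-fold lower at E14 (log2 difference -3.63 ± 0.50 SE, adjusted p = 3.6e-05, limma, 4 arrays). SMPD3, a neutral sphingomyelinase needed for skeletal mineralization, had the lowest fitted value, with log2 differences of -4.32 at E12 and -5.82 at E14 (-5.07 ± 0.52, adjusted p = 1.1e-06). Among genes higher in TC+AC, the ferritin receptor gene SCARA5 was 9.84-fold higher at E12 and at least 15.5-fold higher at E14 (3.89 ± 0.51, adjusted p = 2.4e-05). NBL1, which encodes a secreted BMP antagonist, was 7.84-fold and 7.87-fold higher (2.97 ± 0.50, adjusted p = 0.00054).

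In total 115 of 7805 genes passed adjusted p 0.05 for tissue, 58 higher and 57 lower in TC+AC. All 115 had the same direction at both stages, and 103 were at least 2-fold at both. The other 12 were at least 2-fold at E14 alone. A call rests on the mean of the 2 stages' differences, so the equal directions of all 115 are no independent check. A gene's own disagreement between stages weighed little beside the prior. RTF1 (-0.32 at E12, -4.81 at E14, limma adjusted p = 0.042) and GOLGA3 (-0.57, -4.89, adjusted p = 0.022) were called, both from a TC+AC E14 value below background. The other highest genes were LOC769486, TPPP3, ANKRD39, ACHE, FABP3, CD55, TMEM35B and GSC. FABP3, a fatty acid binding protein gene, was 17.0-fold higher at E12 and 8.73-fold at E14, and the homeobox gene GSC 4.35-fold and 14.9-fold. LOC769486, on its brightest probe set, lay below background in both TC samples and was at least 5.12-fold higher at E12 and at least 22.9-fold at E14, while another probe set had a log2 difference of 0.71 at E12 and lay below background in both E14 samples. The brightest probe sets of TPPP3, ANKRD39, ACHE, CD55 and TMEM35B lay below background in TC at E14; ACHE, the acetylcholinesterase gene, was 4.95-fold higher at E12 and at least 8.34-fold at E14. Another probe set of ANKRD39 had -0.20 and 0.26, and one of ACHE was above background in TC at E14 alone. The other lowest genes were TNN, SLC13A5, ABI3, IFITM5, PCOLCE2, PTH2R, DKK4, MME and IBSP. Another probe set of ABI3 had log2 differences of -2.98 at E12 and -0.08 at E14. SLC13A5, a citrate transporter gene, was 13.0-fold and 38.3-fold lower, and the bone-restricted gene IFITM5 26.5-fold and 8.63-fold lower. TNN, DKK4 and MME lay below background in both TC+AC samples; TNN, which encodes tenascin-W, was at least 9.22-fold lower at E12 and at least 10.3-fold at E14. The count of calls moved with the stage term, the scaling and the choice of genes tested. Fits on 3 arrays lose the stage term as well as an array. Their counts therefore do not isolate dependence on a single array. Fits without a stage term on 3 arrays called 883 genes without TC at E12, 65 without TC at E14, 0 without TC+AC at E12 (570 at an unadjusted p under 0.05) and 0 without TC+AC at E14 (213); all 4 arrays gave 0 with no dim filter (715), 12 with no stage block, 29 from the mean of a gene's probe sets, 217 with the lowest 60% of genes left out, 32 (7 higher, 25 lower) as deposited and 26 (1 higher, 25 lower) scaled on hybridization controls.

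**Figure D2:**
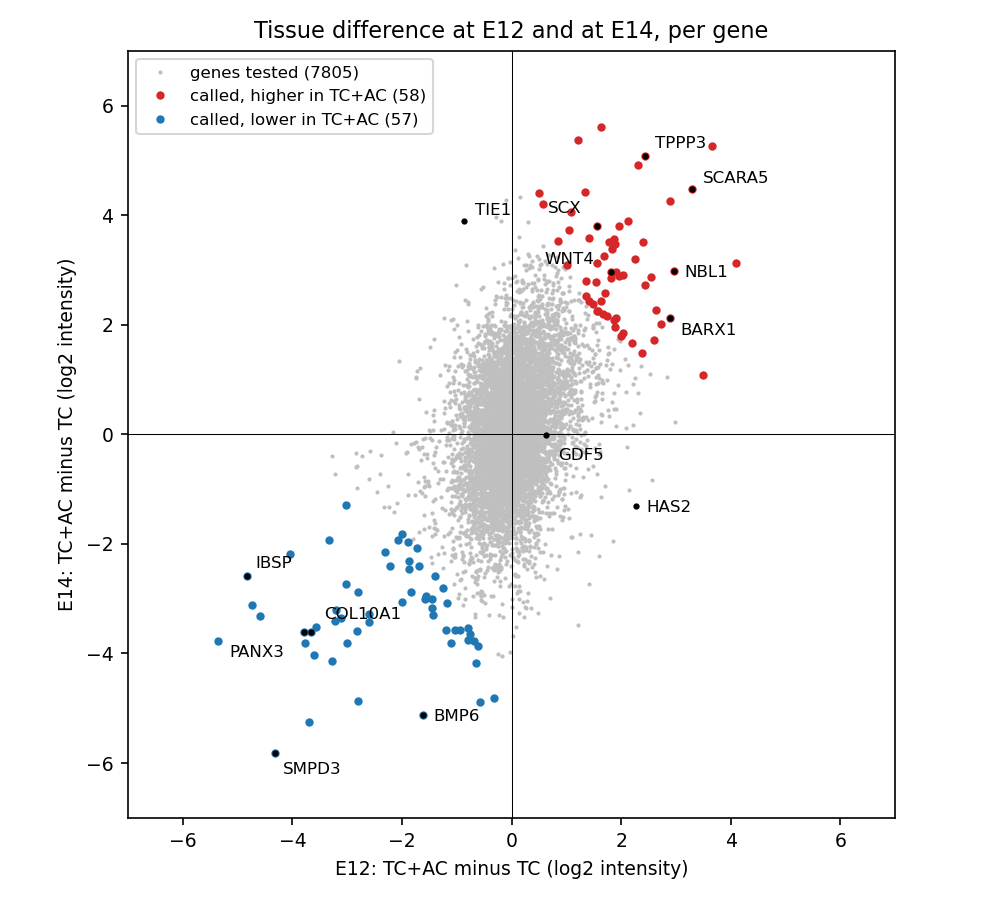
Log2 difference between TC+AC and TC for each of 7805 genes at E12 (horizontal axis) and at E14 (vertical axis); red and blue points are the 58 genes called higher and the 57 called lower, and black points are genes named beside them. The called genes lie in the 2 quadrants of equal sign, and the spread is wider at E14 (SD 1.15) than at E12 (SD 0.61).

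The hypertrophic list had the lowest camera p of the 18 lists. Of its 14 tested genes, 6 were lower in TC+AC and 0 higher (COL10A1, PTH2R, IBSP, PANX3, SPP1 and BMP6); adjusted over the list alone, 10 were lower and 1 higher. PANX3, a channel gene of prehypertrophic chondrocytes, was 13.8-fold and 12.2-fold lower. The list's camera call was downward (adjusted p = 1.1e-14), with adjusted p = 0.79 with an estimated correlation. The osteoblast list, which shares SPP1, IBSP and RUNX2 with it, had 3 of 10 genes lower and 0 higher (IFITM5, IBSP and SPP1), 6 lower when adjusted over the list alone, and a downward camera call (adjusted p = 5.6e-09; adjusted p = 0.79 with an estimated correlation). The matrix protein genes SPP1 and IBSP, which encode osteopontin and bone sialoprotein, were 9.29-fold and 28.3-fold lower at E12 and 10.7-fold and 6.01-fold lower at E14. Members differed between the stages: DMP1 had log2 differences of -3.28 and -0.40 and BGLAP -1.66 and 1.21. In the cartilage matrix list of 20, FMOD was higher and MATN1 lower, against 2 higher and 5 lower adjusted over the list alone, with a downward camera call (adjusted p = 0.0030; adjusted p = 0.79 with an estimated correlation). FMOD, which encodes fibromodulin, was 6.21-fold and 4.82-fold higher, and MATN1, which encodes a matrilin of transient cartilage, was 3.69-fold and 3.93-fold lower on its brightest probe set (adjusted p = 0.044) but had log2 differences of 0.12 and -1.32 on another. COL2A1, the main cartilage collagen gene, had a log2 difference of -0.19 ± 0.50 and SOX9 one of -0.55 ± 0.52, neither past the test.

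Of 16 tested genes of the joint and articular list, 3 were higher in TC+AC and 0 lower, and 4 were higher and 1 lower adjusted over the list alone; its camera call was upward (adjusted p = 0.0021; adjusted p = 0.79 with an estimated correlation). The 3 were TPPP3, a marker of synovial and tendon sheath cells, at 5.40-fold at E12 and at least 9.30-fold at E14, the homeobox gene BARX1 at 7.45-fold and 4.36-fold (adjusted p = 0.0045), and WNT4 at 3.51-fold and 7.75-fold (adjusted p = 0.0089). The established joint markers GDF5, ERG and ENPP2 did not pass, nor did CHRD, SFRP2, NOG or FRZB. Their limma adjusted p ran from 0.20 for CHRD to 0.96 for ERG. GDF5, an early marker of the joint interzone, had log2 differences of 0.62 at E12 and -0.02 at E14, ERG 0.21 and -0.37, and ENPP2, which encodes autotaxin, 0.48 and -1.82. The BMP antagonist gene CHRD had 0.88 and 1.80, SFRP2 -0.14 and 2.65, NOG -0.05 and -0.61 and FRZB 0.14 and -1.10. The second probe set of GDF5 gave 0.40 and -1.14, and that of ERG, below background in TC+AC at E14, gave -0.20 and, with background in place of the dim value, -1.61. WNT9A, IHH, PTHLH and GATA3 were among the dim genes left out of the test. NFIA and GATA3 are known as genes that the study's group followed up, so their values here are not independent evidence: NFIA had 1.49 at E12 and -0.57 at E14, and GATA3 was below background on 3 arrays and had a log2 level of 5.56 in TC+AC at E14. GAPDH had 0.12 and -0.06.

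Signalling lists held calls in both directions. In the BMP list of 21, BMP6 and BAMBI were lower and 0 genes higher, against 3 in each direction adjusted over the list alone, with no camera call (adjusted p = 0.85). BMP6 was 3.05-fold lower at E12 and at least 18.1-fold at E14, and BAMBI, a decoy receptor gene, 8.13-fold and 6.68-fold. In the WNT list of 22, WNT4 and the receptor gene FZD8 were higher and 0 lower, with 2 in each direction adjusted over the list alone (camera adjusted p = 0.64). Of 9 hedgehog and PTHrP genes, the co-receptor genes CDON (5.26-fold and 11.4-fold) and BOC (6.10-fold and 3.28-fold on its brightest probe set) were higher and PTH2R was lower, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.46). A dimmer probe set of BOC had a log2 difference of 1.44 at E12 but was above background in TC and below it in TC+AC at E14. The TGF-beta and FGF list had 0 calls among 17 by either adjustment, over all genes or adjusted over the list alone, yet an upward camera call (adjusted p = 0.028; adjusted p = 0.79 with an estimated correlation); its largest values were those of the FGF target genes ETV5 (0.72 and 2.29, with disagreeing probe sets) and ETV4 (1.51 and 1.30). In the fibrous and tendon list of 26, the tendon transcription factor gene SCX was higher (log2 differences of 1.57 and 3.81, adjusted p = 0.0046), 3 were higher adjusted over the list alone, and the camera call was upward (adjusted p = 0.00092; adjusted p = 0.79 with an estimated correlation). The hypoxia and glycolysis list of 22 had 1 higher (ADM, 2.12-fold at E12 and at least 8.61-fold at E14), 2 adjusted over the list alone, and the immediate early list of 15 had 1 higher by both (HSPB1, 3.43-fold and 11.4-fold), with no camera call (adjusted p = 0.69 and 0.76). Matrix turnover (16 genes) and proliferation (27 genes) had 0 calls, with 0 and 1 higher adjusted over the list alone and camera adjusted p of 0.64 and 0.22.

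Lists for other cell types that a dissection can carry had 0 calls for tissue. Leukocyte genes (12 tested) had 4 higher adjusted over the list alone and an upward camera call (adjusted p = 0.0097; adjusted p = 0.79 with an estimated correlation). Skeletal muscle (14), endothelium (13) and nerve (4) had 0 in either direction adjusted over the list alone, and erythroid genes (11) had 2 higher and 1 lower, with camera adjusted p of 0.31, 0.48, 0.64 and 0.10. With an estimated correlation the adjusted p of all 18 lists lay between 0.79 and 0.88. That version had 1 residual degree of freedom, so these values do not decide for or against a list.

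At E12, 604 genes were at least 2-fold apart, 348 higher and 256 lower in TC+AC; there was no replicate check. The joint and articular list had a median log2 difference of 0.73, above all 10000 matched random lists (percentile 100), and the hypertrophic and osteoblast lists had medians of -1.50 and -1.63, below all of them (percentile 0). Skeletal muscle had -0.38 (percentile 0.74), endothelium -0.33 (percentile 2.06) and cartilage matrix -0.34 (percentile 0.31). Proliferation genes had a median of 0.36 (percentile 99.9) and fibrous and tendon genes 0.39 (percentile 99.98). As deposited, 612 were higher and 169 lower with an all-gene median of 0.20, with median centring 427 and 240, and scaled on hybridization controls 320 and 331 with a median of -0.06.

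At E14, 2804 genes were at least 2-fold apart, 1588 higher and 1216 lower, again without a replicate check. The hypertrophic list stood at a median of -2.22 (percentile 0), cartilage matrix at -1.20 (percentile 0), fibrous and tendon at 0.85 (percentile 99.9) and the joint and articular list at 0.37 (percentile 82.95). Markers of muscle, vessels and blood were on the high side in TC+AC: skeletal muscle genes had a median of 1.12 (percentile 99.9), erythroid genes 0.88 (percentile 97.9), leukocyte genes 0.67 (percentile 93.7) and endothelial genes 0.58 (percentile 90.7). The actin gene ACTA1 had 2.44 and the haemoglobin gene HBBR 3.20, against -0.30 and 0.50 at E12. From E12 to E14 the muscle list changed by a median of -2.41 in TC and -0.53 in TC+AC. These medians were -1.05 and -0.18 for erythroid, -1.15 and -0.09 for leukocyte and -0.84 and 0.05 for endothelial genes. Relative to the other genes after quantile normalization, the E14 differences thus went with lower values in TC at E14 more than with higher values in TC+AC. By measured values, the genes with the largest excess of the E14 over the E12 difference were the endothelial receptor gene TIE1, LOC424918, C12orf10, LBP and TMEM35B, and the opposite extremes were EXOSC9, RTF1, GOLGA3, PARVB and GFPT2. All of these except C12orf10 (4.24) and GFPT2 (-3.95) lay below background on an E14 array. With background in place of dim values the excess was 3.26 for TIE1, 3.31 for LOC424918, 2.92 for LBP and 2.30 for TMEM35B, and -3.14 for EXOSC9, -1.96 for RTF1, -2.03 for GOLGA3 and -2.86 for PARVB, so the order among them is not fixed. Another probe set of TIE1, above background on every array, had tissue differences of 0.10 and 0.32, those of C12orf10 had 0.42 and 1.76 and -0.11 and 2.0, and the probe sets of GFPT2 disagreed. As deposited, the all-gene median at E14 was -1.09 and 225 genes were higher against 4191 lower, and with arrays centred on their medians 935 were higher and 1884 lower.

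Across genes the tissue differences at E12 and E14 had Pearson's r = 0.39 and Spearman's rho = 0.34, from stage pairs that share no array; genes are not independent replicates. At least 2-fold in the same direction at both stages were 303 genes, 194 higher and 109 lower, where independence would give 70.8 and 39.9. In opposite directions were 40 genes, 18 higher and 22 lower at E12, where independence would give 54.2 and 52.1. The split of such genes depended on scaling, with 79 higher and 147 lower as deposited and 30 higher and 293 lower on hybridization controls. With every gene kept r was 0.22.

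**Figure D3:**
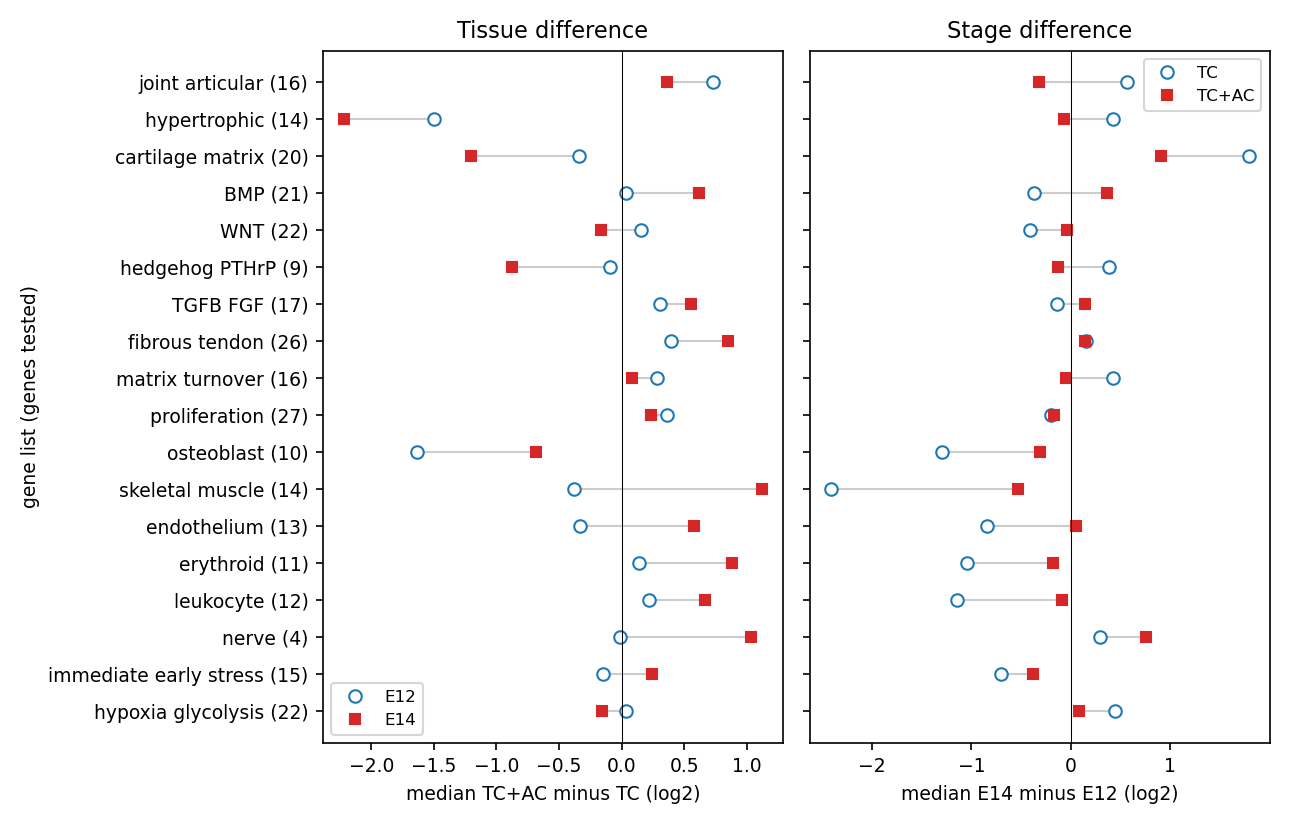
Median log2 difference of each of 18 gene lists: on the left TC+AC minus TC at E12 (circles) and at E14 (squares), on the right E14 minus E12 in TC (circles) and in TC+AC (squares), with the number of genes tested in brackets. Skeletal muscle moves from -0.38 at E12 to 1.12 at E14 on the left, and cartilage matrix stands at 1.79 and 0.91 on the right.

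From E12 to E14, 4 cartilage matrix genes rose in both tissues. MATN3, a matrilin gene, rose by 3.75 on the log2 scale in TC and by 2.29 in TC+AC (3.02 ± 0.51 SE, adjusted p = 0.0098, limma, 4 arrays). ACAN, the aggrecan gene, rose by 3.94 and 1.48 on its brightest probe set (adjusted p = 0.031; -0.20 in TC on another, which was below background in both TC+AC samples), COMP by 4.63 and 1.03 (adjusted p = 0.031) and CHADL, which encodes a collagen-binding matrix protein, by 2.84 and 1.93 (adjusted p = 0.031). TNNT2, a muscle troponin gene, fell by 2.98 in TC and by at least 1.58 in TC+AC (adjusted p = 0.031), and DLK1, a NOTCH-related gene of progenitor cells, had -2.68 and -1.97 (adjusted p = 0.035).

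In total 20 genes passed for stage, 11 higher and 9 lower at E14, and all 20 were at least 2-fold in both tissues by measured values. The others that rose and are named by the rule were COL15A1, PAPSS2, TFEB, C17orf67, PDPN and MCOLN2. PAPSS2, which makes the sulfate donor of proteoglycans, rose by at least 3.22 in TC and at least 0.91 in TC+AC on its brightest probe set, which was below background in both E12 samples. Another probe set of PAPSS2 went the other way, above background in both E12 samples and below it in both E14 samples. COL15A1 rose by at least 3.90 and by 2.02, though its probe sets disagreed on the tissue difference. SNCAIP, OCM3, MAF, PPM1D, TUBAL3, MPRIP and GCHFR fell on their brightest probe sets, while another of MAF had -0.41 and -0.14 and another of MPRIP -0.27 and -0.39. The brightest probe sets of SNCAIP, OCM3, MAF, PPM1D and MPRIP lay below background in TC+AC at E14, that of PPM1D also in TC. With background in place of dim values, their changes in TC+AC were -1.75, -1.82, -1.88, -1.45 and -2.33 in that order. The arginase gene ARG2 had -2.34 and, with background in place of its dim value, -1.93 without passing (adjusted p = 0.055). MCOLN2 and SNCAIP passed for tissue as well (limma adjusted p = 0.0093 and 0.037), each with a TC+AC value below background. With background in place of the dim value, the tissue differences of SNCAIP were -0.80 at E12 and -1.23 at E14. Those of MCOLN2 were -1.58 and -2.41. At least 2-fold the same way in both tissues were 186 genes, 70 higher and 116 lower, where independence would give 30.6 and 87.3, and 87 went opposite ways. The 2 tissues' stage differences correlated across genes at r = 0.07 (rho = 0.03). Fits without a tissue term on 3 arrays called 0 genes without TC at E12 (95 at an unadjusted p under 0.05), without TC at E14 (1125) or without TC+AC at E14 (1987) and 1 without TC+AC at E12; values as deposited gave 0 (370), no dim filter 0 (567), no block 0 (235) and the mean of a gene's probe sets 1.

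Among the lists, cartilage matrix had 4 of 20 genes up and 0 down (MATN3, COMP, ACAN and CHADL), 12 up adjusted over the list alone, and an upward camera call (adjusted p = 1.2e-21; adjusted p = 0.80 with an estimated correlation). All but 2 of its members were higher at E14 in both tissues (18 of 20). Skeletal muscle had 1 of 14 down (TNNT2), 7 down adjusted over the list alone, and a downward camera call (adjusted p = 2.6e-08; adjusted p = 0.80 with an estimated correlation); its median was -2.41 in TC and -0.53 in TC+AC. Osteoblast genes had 0 calls, 4 down adjusted over the list alone, and a downward camera call (adjusted p = 0.00066; adjusted p = 0.80 with an estimated correlation). The endothelium, leukocyte, erythroid and immediate early lists had 0 calls, 0, 1, 1 and 0 down adjusted over the list alone, and downward camera calls (adjusted p = 0.0067, 0.0090, 0.0375 and 0.0375). With an estimated correlation their adjusted p = 0.80, 0.80, 0.82 and 0.80. The medians of the endothelium, leukocyte and erythroid lists in TC were -0.84, -1.15 and -1.05, and in TC+AC 0.05, -0.09 and -0.18. These changes cannot be told apart from RNA integrity. From E12 to E14 the beta-actin 3' over 5' ratio went from 3.26 to 1.99 in TC and from 4.01 to 7.48 in TC+AC. Genomic span correlated with the change across genes at rho = 0.26 in TC and 0.02 in TC+AC. The other 11 lists had 0 calls and camera adjusted p between 0.0577 and 0.87; adjusted over the list alone, BMP had 1 up and 1 down and the rest 0.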

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

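The tests of RNA integrity, scaling, shared spread, soft tissue and joint tissue were chosen after the results were seen; that of dim genes was set before its result.

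Differences of opposite direction at E12 and E14 were found in 40 genes at least 2-fold both ways between TC+AC and TC; with 1 array per group these were not tested. Among the genes of the rule or the lists, the E14 minus E12 change of the tissue difference was -4.69 for EXOSC9, -4.15 for PARVB, -3.58 for HAS2 and -2.57 for WNT11, and 3.20 for AXIN2, 2.87 for BGLAP and 3.0 for MYH1B, on the log2 scale. EXOSC9 and PARVB lay below background in TC+AC at E14, and with background in place of that value their changes were -3.14 and -2.86. HAS2, a hyaluronan synthase gene, had 2.27 at E12 and -1.31 at E14, and the WNT target gene AXIN2 -1.11 and 2.09. The skeletal muscle list had a median of 1.12 at E14 against -0.38 at E12, also not tested. The 3' and 5' probe sets of control transcripts were used in no comparison. Their 3' over 5' ratio in TC+AC at E14 was 7.48 for beta-actin and 3.97 for EF1-alpha, above every other array.

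More genes were at least 2-fold apart at E14 (2804) than at E12 (604). A mere shift in overall array brightness is argued against. The E14 count was 4.64 times the E12 count after quantile normalization and 4.23 times with median centring. Values as deposited and on hybridization controls gave 5.65 and 8.84 times, but they keep such a shift (all-gene E14 medians of -1.09 and -1.64). Scaling by a constant cannot remove wider spread on a dim array, so that effect of brightness cannot be told apart. Dim genes are argued against, since the E14 count was 4.84 times the E12 count among genes above background on all 4 arrays. RNA integrity stays open and may account for part of it. The 2 probe sets of a gene disagreed 2.26 times as much (SD) in the E14 as in the E12 difference. This covers 2555 genes with 2 probe sets past the filter on dim genes, and the ratio was 2.12 with background in place of dim values. The first principal component held 64.2% of this disagreement across arrays. Its loadings were -0.63 in TC E14, -0.10 in TC E12, -0.05 in TC+AC E12 and 0.77 in TC+AC E14. That is the order of the beta-actin ratios (1.99, 3.26, 4.01 and 7.48), though 4 arrays allow no test of it. The part shared by 2 probe sets was also larger, 1.99 times, but a change between the stages cannot be told apart from integrity by this, because the E14 arrays also have the lowest and highest actin ratios.

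Median differences of the muscle, endothelium and erythroid lists between TC+AC and TC were 1.12, 0.58 and 0.88 at E14 and -0.38, -0.33 and 0.14 at E12, with no test within a stage and no call for these lists over both stages. From E12 to E14 their medians changed by -2.41, -0.84 and -1.05 in TC and by -0.53, 0.05 and -0.18 in TC+AC. Relative to the other genes after quantile normalization, the gap at E14 thus lay mostly in lower TC values. The all-gene E14 median was -1.09 as deposited and -1.64 on hybridization controls, so which tissue moved in absolute level cannot be told. The tissue difference was larger at E14 in 84.2% of the 38 tested muscle, endothelial and erythroid genes, with 13 of 14 muscle, 9 of 13 endothelial and 10 of 11 erythroid genes. This share restates the pattern, so soft tissue carried along in different amounts cannot be told apart from other sources by it. RNA integrity cannot be told apart either, as the rise of the difference in the 19 genes with the longest genomic spans had a median of 0.77 with quartiles of -0.04 and 1.57. A change of vessel or muscle content within the tissues between the stages was not tested.

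GDF5, ERG and ENPP2 were not higher in TC+AC at E14. Joint tissue left in the E14 TC dissection may be a source but cannot be told apart from other changes, since 56.2% of the 16 tested joint and articular genes were higher in TC at E14 than at E12. RNA integrity cannot be told apart either: the 2 brightest probe sets of GDF5 and of ERG differed by 1.12 and 2.78 (median 1.95) in the E14 difference, against an upper quartile of 1.34 over those 2555 genes. The gap of ERG rests on a value below background, and with background in place of dim values it was 1.24 against an upper quartile of 1.28, so neither gene exceeded it, while both lay above the median of 0.74. A loss of these markers with stage is an untested biological alternative.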

How the results depend on the processing

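The hybridization-control scaling, the genes above background on all 4 arrays and the E12 pair alone were chosen after seeing the data. Calls for tissue, 115 in the main setting, came to 32 with values as deposited, 0 with no dim filter (13009 genes, 715 at an unadjusted p under 0.05), 217 with the lowest 60% left out, 29 from the mean of a gene's probe sets, 0 over every probe set (23063 probe sets, 1753), 12 with no block, 197 with a trend and robust prior, 26 scaled on hybridization controls and 214 among genes above background, and from 0 to 883 leaving out 1 array. Of the 115, the same genes called again numbered 32, 68, 24, 12, 113, 26 and 72 as deposited, with the lowest 60% left out, from probe set means, with no block, with the trend prior, on hybridization controls and above background. At E12 alone 103 of the 115 were at least 2-fold the same way. The calls used the E12 arrays, so this is no independent check. Calls for stage, 20, came to 0 as deposited, 68 with median centring, 0 with no dim filter, 32 with the lowest 60% left out, 1 from probe set means, 0 over every probe set (1173), 31 with the 40th percentile floor, 0 with no block, 31 with the trend prior, 0 on hybridization controls (77), 33 above background, and from 0 to 1 leaving out 1 array. With 1 array left out, the lone array of a group is assumed to vary like the other group. Those fits also drop the stage or tissue term, so their counts do not isolate the effect of 1 array. The cause of these shifts was not tested.

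Genes at least 2-fold the same way at both stages, 303, were 719 with no dim filter, 197 with the lowest 60% left out, 1077 over every probe set, 1020 at 1.5-fold and 82 at 3-fold, and the stage that keeps both arrays had 604 to 2804. At E12, 604 became 2020, 357, 3060, 1857 and 183 in that order, and at E14, 2804 became 5001, 1785, 9376, 4605 and 1183, and 4416 as deposited and 5754 on hybridization controls. For stage, 186 in both tissues became 542, 97, 923, 704 and 33 in that order, 700 as deposited and 334 with median centring, and 986 to 1750 in the tissue that keeps both arrays. The correlation of 0.39 was 0.22 with no dim filter and 0.22 over every probe set, and 0.34 to 0.45 elsewhere.

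Scaling moved the split of directions. For tissue calls, 58 higher and 57 lower became 7 and 25 as deposited, 58 and 94 with median centring and 1 and 25 on hybridization controls. At both stages, 194 and 109 became 79 and 147 as deposited and 30 and 293 on hybridization controls. At E12, 348 and 256 became 612 and 169 as deposited, and at E14, 1588 and 1216 became 89 and 5665 on hybridization controls. For stage in both tissues, 70 and 116 became 4 and 696 as deposited, 29 and 305 with median centring and 8 and 242 on hybridization controls. The all-gene median was 0.20 at E12 as deposited, and at E14 it was -1.09 as deposited, -0.27 with median centring and -1.64 on hybridization controls. Against that shift, 5 lists had their mean tissue value turned on hybridization controls: joint and articular -0.090, TGF-beta and FGF -0.36, fibrous -0.11, erythroid -0.31 and leukocyte -0.18. The shift moves most genes together, so a mean crossing 0 does not show a list moving against other genes. Camera, which compares a list with the other genes, gave adjusted p of 0.00086, 0.036, 2.9e-05, 0.049 and 0.010 in that order.

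Over the alternatives with all 4 arrays, named genes in the tissue comparison kept direction and side of the threshold 881 times, lost the call 121 times and gained it 58 times; for stage these were 85, 86 and 2. Of the 115 tissue calls, fits on 3 arrays kept 110 without TC at E12, 47 without TC at E14 and 0 without either TC+AC array, and of the 20 stage calls they kept 1 without TC+AC at E12 and 0 otherwise. For lists in the tissue comparison they were 184, 8 and 1, and for stage 176, 21 and 1. No named gene that passed the test turned direction. Passing already uses the arrays of both stages and tissues, so this is no independent check. No paired analysis was possible because each group holds 1 array with the same replicate number, so arrays can be matched only by stage or by tissue, which the main fit does. Of the tested genes, 95.9% were above background in TC+AC at E14 and 99.1% to 99.5% on the other arrays, which limits how far differences in that sample can be measured below background. Several of the strongest tissue calls nevertheless involve such values. Among the 10 highest, LOC769486, SCARA5, TPPP3, ANKRD39, ACHE, CD55 and TMEM35B were below background in TC at E14. Among the 10 lowest, TNN, PCOLCE2, DKK4 and MME were below it in TC+AC at E12.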

Other observations

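The gene families below were defined after the values had been seen, and their differences within a stage have no test. Enzymes and transporters of glycosaminoglycan synthesis and sulfation (17 tested) had a median tissue difference of 0.32 at E12 and -1.05 at E14 on the log2 scale, at percentiles 98.9 and 0.04 of matched random lists, with 13 of 17 above 0 at E12 and 13 of 17 below 0 at E14. From E12 to E14 the same genes had a median of 1.12 in TC (percentile 100) and 0.19 in TC+AC (percentile 88.9); the TC value shares the TC E14 array with the tissue difference at E14. Chaperones and export genes of the endoplasmic reticulum (19 tested) had -0.33 and -0.89, below 0 in 15 of 19 at each stage.

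Nuclear-coded subunits of the respiratory chain (57 tested) had a median tissue difference of 0.00 at E12 and 0.68 at E14 (percentile 100), with 42 of 57 above 0 at E14, and medians from E12 to E14 of -0.63 in TC (percentile 0), which shares the TC E14 array, and -0.07 in TC+AC (percentile 43). Cytosolic ribosomal proteins (61 tested) had 0.01 and -0.01, and proteasome subunits (28 tested) -0.09 and -0.26. Genes of cholesterol synthesis (14 tested) had -0.37 at E12 (percentile 0.44) and 0.11 at E14, with 1 called lower, and HOX genes (8 tested) had 0.21 and -0.04. Longer genomic spans went with lower E14 differences across 7804 genes (rho = -0.25), against -0.14 at E12. For the change from E12 to E14, rho was 0.26 in TC and 0.02 in TC+AC. The TC value shares the TC E14 array with the tissue difference at E14.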
